A study of Mus musculus with 2 samples.

How the data were processed

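Libraries were made from perfused livers of 6-month-old male C57Bl/6 mice, and the mRNA of 4 livers per genotype was pooled into 1 library per genotype, per the labels. The sources used here name FastQC, TopHat2 2.0.8, Cuffdiff 2.1.1 and the mouse build mm10, per the submitters' processing notes, which give them no role or order. Settings, the gene annotation, read length, strandedness and read totals were not given in the sources used here.

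The authors deposited a table in the Cuffdiff layout with 23283 gene rows, which holds an FPKM value per gene for each library, per the file headers. It also holds the authors' p-value and q-value for each gene, a status and a yes or no call, per the file headers. FPKM values are scaled by transcript length and by the library's fragments; the scaling setting the authors chose is not stated. With 1 library per group, such p-values rest on a modelled spread and compare these libraries, not the genotypes. The authors' status was OK for 14868 rows, NOTEST for 8249, LOWDATA for 148, HIDATA for 17 and FAIL for 1. HIDATA rows, with too many fragments at a locus, were listed at 0 in both libraries for 13 genes, Alb, Apoa1, Apob and Scd1 among them, and in 1 library for 4 genes, so a value of 0 there is a failed estimate. The fold change column of the deposited table held cells broken by a spreadsheet and was not used here. In the same way 25 gene names had been turned into dates and were not matched to any list, and 83 rows join several gene names. No column of values was left unmatched to a library.

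Depth was read from the lowest values. Over 2319 rows with few reads in both libraries, ratios gathered at small whole-number ratios around a log2 step of -0.17. If values were scaled by each library's fragments alone, this puts the Alb-Cre library at about 1.13 times the depth of the control library. Of these rows 40.9% lay within 0.05 of such ratios on the log2 scale, where an even spread would give 14.5%. From the lower-valued genes among 83 with 1 annotated transcript, 1 read in a transcript of 1 kb was worth about 0.00836 FPKM in the control library. On that estimate 1 FPKM in 1 kb stands for about 119.6 reads. The higher values among the 83 genes were left out, which lowers the worth of 1 read and raises the implied depth. If the estimate holds, counting error is small for most measured genes. The spread between mice, which pooling hides, is unknown.

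The difference between libraries was log2((Alb-Cre FPKM + 1)/(control FPKM + 1)). A gene was measured if its status was OK and it had 1 FPKM or more in at least 1 library, which left 11406 genes, and it was called higher or lower at a log2 ratio of 1 or more in size. No p-value was computed, because each genotype has 1 library. For 40 gene lists chosen before the data were examined, covering insulin-regulated metabolism, liver cell types, sex-biased genes, inflammation and stress, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A list stood apart below the 2.5th or above the 97.5th percentile, and lists with under 5 measured members were given as values only. Such a percentile describes these libraries, not the genotypes. Tested on simulated lists drawn from the 11406 genes of this comparison, 200 per setting, unshifted lists of 20 genes were called high in 3% and low in 1.5% of cases, and lists shifted by 0.25 were called in 89%. For lists of 7 genes the shares were 2.5% and 3% unshifted, 34.5% at a shift of 0.25 and 92.5% at 0.5. In these simulations ratios were shuffled within expression bins and genes were drawn independently. Unshifted shares near 2.5% per side therefore follow by construction. They give no error rate for the real lists, whose members may vary together.

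The genes named were set by rule before the data were examined: the Akt genes, the 12 highest and 12 lowest ratios, and the 3 members with the largest ratios in size of each list that stood apart and of the FoxO, gluconeogenesis, glycolysis, fatty acid synthesis and cytokine lists. This gave 84 genes, a few of which are not reported here. After the values were seen, the 12 highest and 12 lowest ratios were ranked again without short RNA features. Other members named with a list were also chosen after their values were seen, as examples of its higher and lower genes or as genes well known for the list's function.

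Gene positions are those of GENCODE vM21 on mm10, counted from 1. Of 20799 gene symbols with 1 GENCODE gene, 99.1% lay at an overlapping position in the deposited table. The alternatives tried were pseudocounts of 0.1 and 5 FPKM, no minimum and a minimum of 5 FPKM, libraries rescaled to the same sum, ratios centred on genes with 10 FPKM or more in both libraries, rows of any status, limits of 1.5-fold and 4-fold, the mean of a list, lists without shared members and a q-value limit of 0.01. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.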

Results

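RNA was sequenced from perfused livers of 6-month-old male C57Bl/6 mice of 2 genotypes. Every mouse was labelled as lacking Akt2 in all tissues and as carrying floxed Akt1 alleles. Akt1 and Akt2 encode serine/threonine kinases that act downstream of insulin and growth factor receptors. Mice of the second group were labelled as also carrying Alb-Cre, a recombinase driven by the albumin promoter that removes floxed sequence in hepatocytes. The mRNA of 4 livers per genotype was pooled into 1 library, so there were 2 libraries, called here the control library and the Alb-Cre library after their labels. By its labels, the comparison asks how livers of Akt2-null mice differ when Akt1 is also targeted in hepatocytes. Because each genotype is 1 pooled library, no difference below has a replicate check, and no error can be given for any value. The values are the authors' FPKM (fragments scaled by transcript length and by the library's fragments, with a scaling setting that is not stated). Of 23283 gene rows, 10754 had 1 FPKM or more in the control library and 11244 in the Alb-Cre library. Read totals per library were not given in the sources used here. The step size of the lowest values put the Alb-Cre library at about 1.13 times the depth of the control library. That figure holds if values were scaled by each library's fragments alone. Differences are log2 ratios of Alb-Cre over control with 1 FPKM added to each value, which understates the ratio of weakly expressed genes.

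Akt1 was lower in the Alb-Cre library, and neither Akt1 nor Akt2 differed by 2-fold. Akt1 (mm10 chromosome 12, 112653821 to 112674884) had 23.7 FPKM in the control library and 17.1 in the Alb-Cre library, a log2 ratio of -0.45. Akt2 (chromosome 7, 27591552 to 27640826) had 37.5 and 33.5 FPKM, a log2 ratio of -0.16, in libraries that were both labelled as Akt2-null. Which exons the null and floxed alleles remove was not given in the sources used here, and these values cover whole genes, so they are a weak check of the labels.

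Among 11406 measured genes, 428 were at least 2-fold higher in the Alb-Cre library, 209 were at least 2-fold lower and 10769 lay between. Gpx3, which encodes a secreted glutathione peroxidase, had 1.78 FPKM in the control library and 821 in the Alb-Cre library, a log2 ratio of 8.21. The imprinted non-coding RNA H19 had 0.0549 and 206 FPKM (log2 ratio 7.62). Igfbp1, a secreted binding protein for insulin-like growth factors, had 29.2 and 3618 FPKM (6.90), and the trefoil factor gene Tff3 had 12.5 and 1114 FPKM (6.37). These 4 genes and 8 snoRNA or microRNA features made up the 12 highest ratios. The 8 features, Snord37, Snord19, Snord66, Snord69, Mir5119, Snord38a, Snord72 and Mir186, were listed at 0 in the control library and between 73.6 FPKM for Mir186 and 1864 FPKM for Snord37 in the Alb-Cre library. The 12 lowest ratios were all short RNA features listed at 0 in the Alb-Cre library, namely Mir5100, Mir1968, Scarna2, Mir145, Mirlet7b, Snord73a, Mir199a-1, Mir3112, Mir5123, Mir1839, Mir328 and Mir25, with control values from 148 FPKM for Mir5100 to 17.2 FPKM for Mir25. Such features, named Mir, Snor, Scarna or Rnu, gave 47 of the higher and 52 of the lower genes. Without them 381 genes were higher and 157 lower.

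A ranking without the short features, chosen after the values were seen, added 8 genes to the highest 12. The leptin receptor gene Lepr had 1.35 FPKM in the control library and 72.8 in the Alb-Cre library (log2 ratio 4.97). The glypican gene Gpc3 had 0.453 and 45.9 FPKM (5.01), and the anion transporter gene Slc4a9 had 0.161 and 32.3 FPKM (4.84). The other 5 belong to the female-biased liver genes described below. The lowest ratios of this ranking were those of Mug2, a murinoglobulin secreted by hepatocytes, with 52.4 and 3.45 FPKM (-3.58), and of Cfd, which encodes complement factor D, with 6.70 FPKM in the control library and listed at 0 in the Alb-Cre library. Major urinary protein genes supplied 3 of the lowest 12, with Mup21 at 353 and 56.5 FPKM (-2.62), Mup7 at 965 and 239 FPKM (-2.01) and Mup12 at 34.0 and 8.48 FPKM (-1.88). The remaining 7 were Cml5, Slco1a1, the lipid droplet gene Fitm1 (60.5 and 14.3 FPKM, -2.01), the ribosomal protein gene Rps27 (17.2 and 3.60 FPKM, -1.98), Serpina4-ps1, Gm13152 and C730036E19Rik. The Mup, Sult2a and Cyp2b genes have near-identical copies between which reads could have been divided, so values of single members are uncertain. Copies of the other named genes were not searched for, so the same limit may apply to them, Rps27 and Cyp2a4 included. Rps27 was not called different in the authors' deposited table (q-value 0.999).

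The median log2 ratio was -0.06 over all measured genes and -0.13 over the 4964 genes with 10 FPKM or more in both libraries. Of the genes that differed by 2-fold, 67.2% were higher in the Alb-Cre library. With ratios centred on those 4964 genes, 563 genes were higher and 159 lower, so that 78.0% were higher. Log2 values of the libraries correlated across genes with a Pearson r of 0.951, and genes are not independent replicates.

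**Figure D1:**
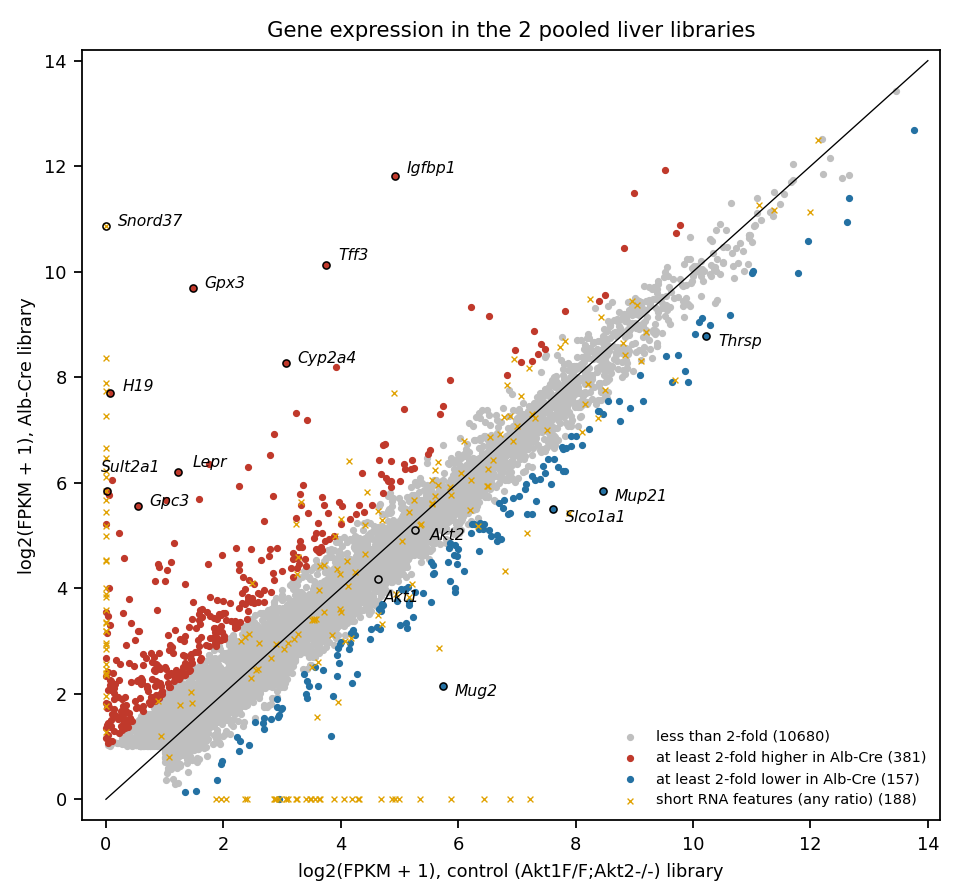
Each point is a measured gene, with log2(FPKM + 1) in the control library on the x axis and in the Alb-Cre library on the y axis, and the line marks equal values. Red and blue points are the 381 and 157 genes other than short RNA features that differed by at least 2-fold, crosses are the 188 short RNA features, many of which lie on an axis at a value of 0, and circled genes are named in the text.

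The authors' deposited table called 100 genes different between these 2 libraries, 89 of them higher and 11 lower in the Alb-Cre library. Igfbp1, Gpx3, Tff3, Gpc3, Lepr and Mug2 were among them, each at the lowest q-value in the authors' deposited table, 0.0109, which 68 genes shared. Other genes with large ratios were not called: in the authors' deposited table the q-value was 0.0851 for H19, 0.221 for Sult1e1, 0.497 for Cyp2b13 and 0.999 for Sult2a1. All 86 of the called genes that were also measured here differed by at least 2-fold. Of the genes called in the authors' deposited table, 14 were under 1 FPKM in both libraries and 20 were listed at 0 in the control library. These p- and q-values compare the 2 libraries and not the genotypes, since no spread between mice entered them.

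Genes described as induced by FoxO factors, transcription factors that Akt holds out of the nucleus, were higher in the Alb-Cre library as a group. Of 20 measured FoxO targets, 6 were at least 2-fold higher and 2 at least 2-fold lower. Besides Igfbp1, the insulin receptor substrate gene Irs2 had 2.42 FPKM in the control library and 13.2 in the Alb-Cre library (log2 ratio 2.05), and Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, had 2.96 and 12.5 FPKM (1.77). The growth arrest gene Gadd45a went the other way, with 11.98 and 4.45 FPKM (-1.25), as did Pik3r1, the regulatory subunit of PI3 kinase (25.1 and 12.02 FPKM). The list's median log2 ratio of 0.31 lay above the range of -0.23 to 0.07 that held 95% of 10000 random lists of like expression. These percentiles describe the 2 libraries only, and members of a list are not independent of each other.

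Some genes of glucose output were higher and some of glucose use lower, while neither list as a whole differed by 2-fold. Of 12 measured gluconeogenesis genes, 4 were at least 2-fold higher and 0 lower: the aminotransferases Got1 (155 and 470 FPKM, log2 ratio 1.59) and Tat (874 and 1883 FPKM, 1.11), mitochondrial Pck2 (0.739 and 2.73 FPKM, 1.10) and glucose-6-phosphatase G6pc (178 and 367 FPKM, 1.04). The list's median of -0.07 lay within the range of random lists, its sign turned to 0.06 with centred ratios, and its mean was 0.37. Pck1, the cytosolic carboxykinase, was listed at 986 FPKM in the control library and at 0 in the Alb-Cre library with a failed status, and was not used. In the glycolysis list, the liver pyruvate kinase gene Pklr was lower in the Alb-Cre library (217 and 101 FPKM, -1.09). The pyruvate kinase gene of other tissues, Pkm2, had 6.95 and 14.7 FPKM (0.98). Of the 17 measured glycolysis genes, 0 were 2-fold higher and 2 were 2-fold lower, while the median of 0.21 lay above the range of random lists (-0.28 to 0.10). The list's mean, 0.08, did not lie outside that of random lists.

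Lipid and sterol synthesis genes were lower in the Alb-Cre library. Of 22 measured fatty acid synthesis genes, 3 were at least 2-fold lower: Thrsp, a lipogenic regulator (1200 and 440 FPKM, log2 ratio -1.44), malic enzyme Me1 (177 and 72.1 FPKM, -1.29) and Srebf1, which encodes the lipogenic transcription factor SREBP1 (158 and 65.6 FPKM, -1.25). Fatty acid synthase, Fasn, had 146 and 78.9 FPKM (-0.88). The lipase gene Pnpla5 was the single member at least 2-fold higher, from a low level (0.208 and 2.73 FPKM, 1.63). The list's median of -0.57 lay below the range of random lists (-0.29 to 0.05). Cholesterol synthesis genes had a median of -0.58 against a random range of -0.30 to 0.00, and 1 of 23 was at least 2-fold lower. That gene was Insig1, a sterol-regulated retention protein (336 and 163 FPKM, -1.04), and the sterol carrier gene Stard4 had 60.0 and 33.0 FPKM (-0.84). Scd1 was listed at 0 in both libraries with a failed status, as were other very abundant genes, and was not used.

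Lipid storage genes went both ways. Of 14 measured members, 4 were at least 2-fold higher, among them lipoprotein lipase Lpl (3.805 and 60.2 FPKM, log2 ratio 3.67) and the apolipoprotein gene Apoa4 (91.3 and 569 FPKM, 2.63), and 4 were at least 2-fold lower, among them Fitm1 and the lipase inhibitor gene G0s2 (224 and 73.7 FPKM, -1.59). The median of -0.09 lay within the range of random lists, turned to 0.05 with centred ratios and was 0.15, above the range, with a minimum of 5 FPKM. Fatty acid oxidation and ketogenesis genes had a median of -0.15, within the range of random lists, with 2 of 21 higher and 1 lower. Bile acid genes had a median of -0.44, below the random range of -0.30 to 0.02, with 2 of 20 higher and 2 lower. The uptake transporter Slco1a1, also a male-biased gene, had 195 and 44.4 FPKM (-2.11), and the export transporters Abcc4 (1.11 and 6.11 FPKM, 1.75) and Ostb (0.529 and 3.58 FPKM, 1.58) were higher. With the mean, -0.22, or without the members that other lists share, -0.17, the bile acid list no longer lay outside the random range.

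Liver genes that are higher in females were higher in the Alb-Cre library, and those higher in males were lower. Of 26 measured female-biased genes, 18 were at least 2-fold higher in the Alb-Cre library and 0 were lower, with a median log2 ratio of 1.59 against a random range of -0.18 to 0.09. The oestrogen sulfotransferase gene Sult1e1 had 0.0801 FPKM in the control library and 65.1 in the Alb-Cre library (5.94), Sult2a1 had 0.00833 and 56.8 FPKM (5.84) and the cytochrome P450 gene Cyp2b13 had 0.0383 and 53.2 FPKM (5.71). Cyp2a4 had 7.38 and 307 FPKM (5.20), and Sult2a2 was listed at 0 in the control library and had 36.3 FPKM in the Alb-Cre library. Sult1e1, Sult2a1, Cyp2b13, Sult2a2 and other members passed the minimum of 1 FPKM only through the Alb-Cre library. Such a minimum favours genes higher in that library, though the female-biased list also stood apart with no minimum. Of 22 measured male-biased genes, 16 were at least 2-fold lower and 0 higher, with a median of -1.25 against -0.26 to 0.04. Cml5 had 13.3 and 1.298 FPKM (-2.64), and Mup21 and Slco1a1 came next. Of 13 measured Mup genes, 9 were at least 2-fold lower, with a median of -1.68 that was -1.61 with libraries rescaled to the same sum and -1.54 with centred ratios. The 4 measured Y-linked genes had a median log2 ratio of -0.29 without a pseudocount, with Ddx3y at 25.9 and 19.8 FPKM and Eif2s3y at 42.3 and 33.6 FPKM. Xist, expressed from the inactive X chromosome of females, had 0.0246 and 0.0166 FPKM.

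**Figure D2:**
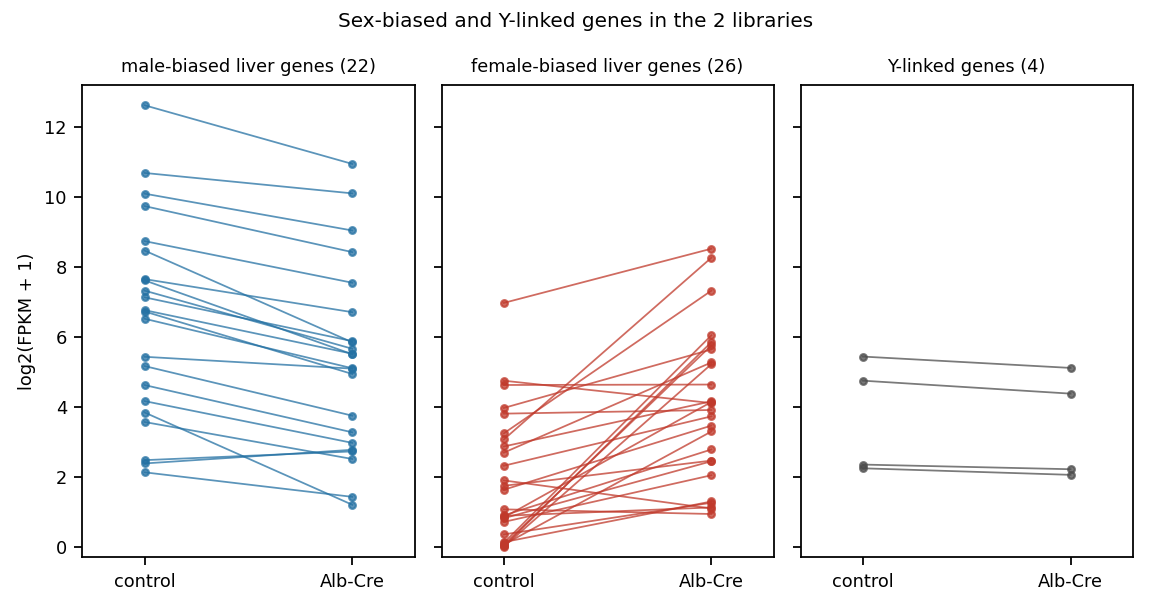
Lines join each gene's log2(FPKM + 1) in the control library to that in the Alb-Cre library, for 22 male-biased, 26 female-biased and 4 Y-linked genes. Of the male-biased genes 16 were at least 2-fold lower in the Alb-Cre library, of the female-biased genes 18 were at least 2-fold higher, and no Y-linked gene differed by 2-fold.

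In the growth hormone and IGF axis, 2 of 13 measured genes were at least 2-fold higher and 3 were lower. The binding protein genes Igfbp2 (507 and 2877 FPKM, log2 ratio 2.501) and Igfbp3 (5.0 and 12.4 FPKM, 1.15) were higher. The growth hormone receptor gene Ghr (352 and 156 FPKM, -1.17), Igf1 (255 and 117 FPKM, -1.11) and Igfals, the acid-labile subunit that carries IGF in serum (84.8 and 33.7 FPKM, -1.31), were lower. The list's median of -0.21 lay within the range of random lists, and was -0.44, below that range, with a minimum of 5 FPKM.

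Markers of hepatocytes lay between the 2-fold limits. Of 19 measured hepatocyte markers, 0 were 2-fold higher or lower and the median log2 ratio was -0.25, within the random range of -0.32 to 0.11. The transport protein Ttr (6489 and 3627 FPKM, -0.84) and the transcription factors Cebpa (273 and 153 FPKM, -0.83) and Foxa2 (20.8 and 10.9 FPKM, -0.87) had the lowest ratios. Alb, Apoa1, Apob, Trf and Ahsg were listed at 0 in both libraries and were not used. Genes of pericentral hepatocytes had a median of -0.21, with 1 of 17 higher and 2 lower, and genes of periportal hepatocytes had a median of 0.02, with 1 of 16 higher and 1 lower; neither lay outside the range of random lists. The pericentral list lay below it with a minimum of 5 FPKM (-0.38) and with a pseudocount of 5 FPKM (-0.19).

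Markers of macrophages and antigen-presenting cells were higher in the Alb-Cre library. Of 14 measured monocyte and recruited macrophage markers, 9 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.15 against a random range of -0.20 to 0.23, which was 0.75 with no minimum and 0.69 with a pseudocount of 5 FPKM. The lipopolysaccharide receptor gene Cd14 had 1.14 and 6.55 FPKM (1.82), the lysozyme gene Lyz2 had 27.8 and 84.4 FPKM (1.57) and the galectin gene Lgals3 had 2.90 and 10.3 FPKM (1.53). Of 10 measured class II antigen presentation genes, 6 were higher and 0 lower, with a median of 1.27 against -0.24 to 0.29. H2-Eb1 (12.1 and 47.1 FPKM, 1.88), H2-Ab1 (19.7 and 71.7 FPKM, 1.82) and H2-Aa (24.0 and 84.8 FPKM, 1.78) led. The class II median was 0.70 over 14 members with no minimum and 0.71 with a pseudocount of 5 FPKM. Batf3, Cd86 and Clec9a passed the minimum of 1 FPKM only through the Alb-Cre library. Of 16 resident Kupffer cell markers, 5 were higher, among them the scavenger receptor gene Marco (1.77 and 9.74 FPKM, 1.95) and the complement gene C1qb (26.2 and 66.9 FPKM, 1.32). The Kupffer list's median was 0.86 against -0.25 to 0.06, and its single lower member, complement C6 (90.7 and 33.4 FPKM, -1.41), is also in the male-biased list.

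Genes of inflammatory mediators were also higher in the Alb-Cre library. The 7 measured T and NK cell markers, of 24 in the list, all lay between the 2-fold limits, with a median log2 ratio of 0.77 against a random range of -0.14 to 0.64. Their levels were low, from 0.298 FPKM for Gzmb to 0.828 for Nkg7 in the control library, so they passed the minimum of 1 FPKM only through the Alb-Cre library, as did Thy1 (0.383 and 1.48 FPKM) and Gzma (0.315 and 1.26 FPKM). Such a minimum favours genes higher in that library, and the median was 0.37 with no minimum and 0.24 with a pseudocount of 5 FPKM. The 3 measured B lineage markers had a median of 0.72 and the 4 measured neutrophil markers a median of 1.83, of which S100a8 (2.01 and 9.60 FPKM), S100a9 and Lcn2 were at least 2-fold higher; lists this short were not set against random lists. Of 18 measured cytokine and chemokine genes, 2 were higher and 0 lower, the T cell chemoattractant Ccl5 (2.03 and 9.06 FPKM, 1.73) and Ccl6 (4.14 and 11.98 FPKM, 1.33), and the monocyte attractant Ccl2 had 0.779 and 2.17 FPKM (0.84). That list's median was 0.54 against -0.17 to 0.17, from the 18 of 36 members that passed the minimum. Of 24 interferon-stimulated genes, 3 were higher and 0 lower, the guanylate-binding protein genes Gbp2 (2.04 and 11.1 FPKM, 1.99) and Gbp3 (2.59 and 9.89 FPKM, 1.6002) and Usp18, which removes ISG15 from proteins (5.83 and 23.5 FPKM, 1.85), with a median of 0.41 against -0.16 to 0.12.

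Markers of the liver's stromal cells were higher alongside the immune markers. Of 19 measured endothelial markers, 1 was at least 2-fold higher, the hyaluronan receptor gene Lyve1 (1.11 and 4.11 FPKM, log2 ratio 1.27), and 0 were lower, with a median of 0.47 against a random range of -0.20 to 0.09. Rspo3 had 2.46 and 4.75 FPKM (0.73) and Stab2 had 2.27 and 0.980 FPKM (-0.72). Of 25 stellate cell and fibrosis genes, 1 was higher, the matricellular gene Ctgf (2.43 and 7.29 FPKM, 1.27), and 0 were lower, with a median of 0.48 against -0.13 to 0.20. The intermediate filament gene Vim (7.96 and 16.1 FPKM, 0.93) and the matrix proteoglycan gene Lum (4.04 and 8.505 FPKM, 0.92) followed. Of 7 measured bile duct and progenitor markers, the keratin gene Krt23 was higher (1.23 and 28.1 FPKM, 3.71), and the list's median of 0.17 lay within the range of random lists, while its mean of 0.71 lay above that of random lists. Values for tissues carried along were a median of -0.03 for 3 erythroid genes, -0.01 for 2 pancreas genes and -0.33 for 3 adipose genes, with the erythroid haem synthesis gene Alas2 at 117 and 41.8 FPKM (-1.46) and the globin gene Hbb-b2 at 1.15 and 2.98 FPKM (0.89).

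Genes of fetal liver and liver tumours were higher in the Alb-Cre library. Of 18 measured members, from a list of 28, 11 were at least 2-fold higher and 0 lower. Their median log2 ratio was 1.37 against a random range of -0.16 to 0.20. H19, Tff3 and Gpc3 led, and the alpha-fetoprotein gene Afp had 0.879 and 4.70 FPKM (1.601). H19, Gpc3, Afp and other members were under 1 FPKM in the control library and passed the minimum only through the Alb-Cre library. Such a minimum favours genes higher in that library, though the list also stood apart with no minimum. Of 18 measured cell cycle genes, 1 was higher, the cyclin gene Ccnd1 (11.8 and 32.2 FPKM, 1.38), and the list's median of 0.26 lay within the random range of -0.13 to 0.29. Of 16 p53 target and senescence genes, 4 were higher and 0 lower, among them the cell cycle inhibitor Cdkn1a (0.761 and 5.49 FPKM, 1.88) and the antiproliferative gene Btg2 (11.9 and 52.2 FPKM, 2.05), and the median of 0.12 lay within the random range of -0.21 to 0.13. The cell cycle and p53 medians passed the upper end of their random ranges with a pseudocount of 0.1 FPKM, at 0.44 and 0.15, as did the cell cycle median with no minimum (0.35) and the p53 mean (0.50).

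Among stress lists, immediate early genes stood apart most. That list had been set to cover the stress of tissue handling. With 1 pool per genotype, a difference in handling cannot be told apart from one of genotype. Of 18 measured, 7 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.57 against a random range of -0.22 to 0.10. The nuclear receptor gene Nr4a1 had 2.93 and 23.8 FPKM (2.66). The AP-1 genes Fosl2 and Fos had 1.79 and 12.4 FPKM (2.26) and 5.21 and 22.3 FPKM (1.91). More strongly expressed members went both ways within the 2-fold limits. Zfp36 (138 and 102 FPKM, -0.43), Dusp1 (-0.31) and Ier2 (-0.21) were lower in value, and Junb (0.42), Jund (0.32) and Jun (0.26) higher. Nr4a2, Fosb and Klf4 passed the minimum of 1 FPKM only through the Alb-Cre library, though the list also stood apart with no minimum. Of 31 acute phase genes, 5 were higher and 1 lower. The metal-binding metallothionein genes Mt2 (14.1 and 294 FPKM, 4.29) and Mt1 (73.5 and 642 FPKM, 3.11) and the interleukin-1 receptor antagonist gene Il1rn (0.859 and 20.9 FPKM, 3.56) led, the orosomucoid gene Orm2 (15.2 and 45.9 FPKM, 1.53) was also higher, and the serum amyloid gene Saa4 (228 and 99.8 FPKM, -1.18) was the lower member. The other 25 members lay between the 2-fold limits and went both ways. Among them Orm1 (986 and 650 FPKM, -0.60), Saa1 (-0.63), Saa2 (-0.58), Saa3 (-0.78) and Crp (-0.53) were lower in value. Lbp (0.59), Hamp (0.48) and Hpx (0.33) were higher in value. The acute phase median of 0.03 lay just above the random range of -0.25 to 0.02, and no longer did with a minimum of 5 FPKM or without shared members. NRF2 targets had a median of 0.22 against -0.27 to 0.03, with 2 of 20 higher, the aldo-keto reductase gene Akr1b7 (0.243 and 22.7 FPKM, 4.25) and Abcc4, and with Me1 lower. Their mean, 0.35, did not lie outside that of random lists.

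Circadian clock genes had a median log2 ratio of -0.35 against a random range of -0.26 to 0.05, with 0 of 15 differing by 2-fold. That list had been set to cover the time of day of collection, a difference in which cannot be told apart from one of genotype either. The lowest were Bhlhe40 (90.2 and 52.8 FPKM, -0.76), Hlf (20.4 and 12.3 FPKM, -0.69) and Bhlhe41 (4.25 and 2.45 FPKM, -0.61), and the list's mean, -0.28, did not lie outside that of random lists. The unfolded protein and integrated stress response list did not stand apart, with a median of -0.14, 4 of 21 higher and 0 lower, although Ddit4, an inhibitor of mTORC1, had 4.34 and 77.8 FPKM (3.88); with a minimum of 5 FPKM or without shared members the median was -0.29, below the random range. Drug-metabolising enzymes had a median of -0.17, with 3 of 23 higher, among them Cyp2a5 (736 and 3898 FPKM, 2.40), and 1 lower. Apoptosis genes had a median of 0.06 with 0 of 18 higher and 1 lower, and with no minimum a median of 0.13 that lay above the random range. PI3K and insulin signalling components had a median of -0.09, or 0.04 with centred ratios, with 2 of 26 higher and 2 lower; the kinase gene Sgk1 had 9.75 and 146 FPKM (3.77) and Foxo1 had 11.4 FPKM in both libraries. Of the 40 lists, 15 lay above and 5 below the range of random lists, 14 lay within it and 6 were too short to be placed.

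**Figure D3:**
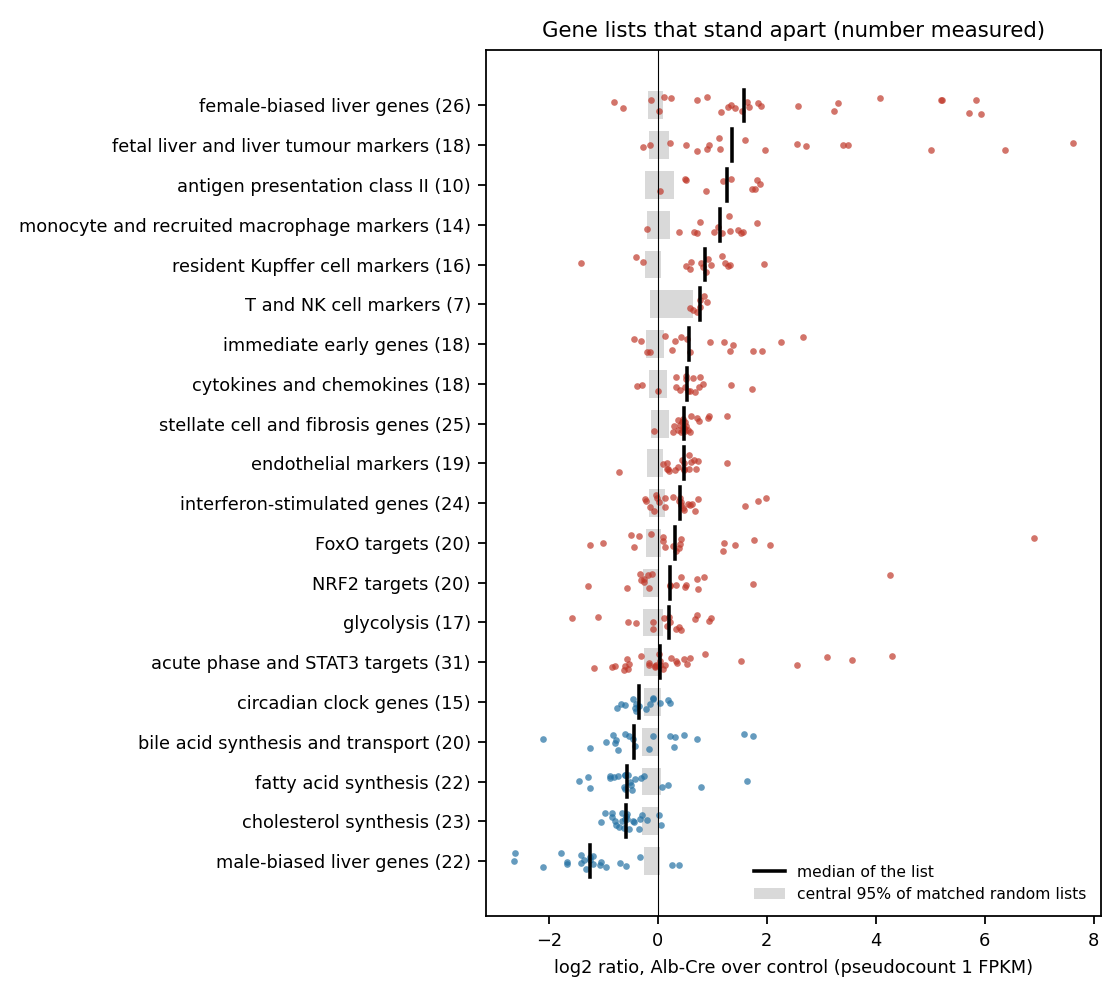
Points are the log2 ratios (Alb-Cre over control, 1 FPKM added) of the measured members of the 20 lists that lay outside the range of random lists, black bars are list medians and grey bars hold the central 95% of random list medians. Female-biased genes, with a median of 1.59, and male-biased genes, with a median of -1.25, lie at the ends.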

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

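The rows with the authors' status LOWDATA entered none of the report's comparisons and were counted only in the alternative with rows of any status, and 25 of those considered had 1 FPKM or more in at least 1 library and a value above 0 in both. Of these, 4 had at least 2 times the control value in the Alb-Cre library and 3 had at least 2 times the Alb-Cre value in the control library. Mir719 had 3.31 FPKM in the control library and 17.5 in the Alb-Cre library, and Snora26 had 0.857 and 2.29 FPKM; both are short RNA features. Gm7334 had 2.76 and 8.67 FPKM, and Gm6644 had 5.73 and 13.8 FPKM. No biological explanation was tested for these values.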

How the results depend on the processing

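With 1 library per genotype no library could be left out in turn, and the spread between mice is unknown; depth limits the weakly expressed genes, with 1 read in 1 kb worth about 0.00836 FPKM in the control library. No paired analysis was possible because each genotype has 1 pooled library and the results come from no test. The number of genes at least 2-fold higher, 428, was 769 with a pseudocount of 0.1 FPKM, 178 with 5 FPKM and 283 with a minimum of 5 FPKM, while the number lower, 209, stayed within 1.5 times. At a 1.5-fold limit 1012 genes were higher and 661 lower, and at a 4-fold limit 117 and 45, as fewer or more genes pass by construction. The libraries rescaled to the same sum gave 471 and 182 genes (72.1% higher), and rows of any status 441 and 219. Among the authors' calls, 0 had a q-value of 0.01 or less, because the lowest q-value in the authors' deposited table was 0.0109, shared by 68 genes. That limit therefore removed every call at once and says nothing about single calls. Of the 34 lists placed among random lists, 21 kept their call under every alternative that gave a value, and 13 did not; the cause was not tested. With the mean, glycolysis (0.080), bile acid genes (-0.22), NRF2 targets (0.35) and clock genes (-0.28) no longer stood apart, and bile duct markers (0.71) and p53 targets (0.50) did. With a minimum of 5 FPKM the acute phase list (0.030) no longer stood apart, and lipid storage (0.15), pericentral genes (-0.38), the growth hormone axis (-0.44) and the unfolded protein list (-0.29) did. Without shared members the bile acid (-0.17) and acute phase (0.024) lists no longer stood apart and the unfolded protein list (-0.29) did. A pseudocount of 0.1 FPKM set cell cycle genes (0.44) and p53 targets (0.15) apart, one of 5 FPKM pericentral genes (-0.19), and no minimum cell cycle (0.35) and apoptosis genes (0.13). Too few members were left for a call of the T and NK list with a minimum of 5 FPKM, and of the bile duct list there and without shared members. Of the values of single named genes under other settings, 620 kept their side of the 2-fold limit, 14 dropped below it and 13 passed it, and none that had passed it changed sign.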

Other observations

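The tests of the imprinted and glucocorticoid-induced genes, of cell shares, of blood and of short features were chosen after the values they concern had been seen; those of the Y-linked, ribosomal protein and oxidative phosphorylation genes were set before.

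Several genes outside the 40 lists, picked after their values were seen, had large ratios. Ldhb, the lactate dehydrogenase subunit of heart, had 2.39 FPKM in the control library and 80.8 in the Alb-Cre library, and Slc25a4 and Cox7a1, the heart and muscle forms of the mitochondrial nucleotide carrier and of a cytochrome oxidase subunit, had 6.18 and 53.1 FPKM and 8.99 and 46.8 FPKM. Pygb, the brain form of glycogen phosphorylase, had 1.07 and 7.62 FPKM. Ppp1r3g, which directs phosphatase to glycogen, had 5.93 and 90.9 FPKM, and Txnip, an inhibitor of thioredoxin, had 56.9 and 246 FPKM. Among secreted regulators of the activin family, the activin antagonist gene Fst had 1.54 and 16.0 FPKM and Inhbe, an activin subunit gene of hepatocytes, had 45.4 and 12.3 FPKM. Cd63, a late endosome protein, had 6.24 and 120.2 FPKM, the succinate receptor gene Sucnr1 had 57.4 and 16.7 FPKM, and Csad, an enzyme of taurine synthesis, had 144 and 41.3 FPKM.

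Ribosomal protein genes were predicted to be lower if less Akt lowers expression of the translation machinery, and the prediction failed in these 2 libraries. Of 81 measured, 75 had a ratio above 0, with a median log2 ratio of 0.30 against a random range of -0.22 to 0.00, and 0.36 and 0.43 with rescaled libraries and centred ratios. Rps27, at -1.98, was the single member at least 2-fold lower. Oxidative phosphorylation genes were predicted to be higher beside Ppargc1a, and their median of 0.092 lay above the random range of -0.21 to -0.02, with 59 of 85 above 0 and Cox7a1 alone at least 2-fold higher. The prediction held, but the size is small and Ppargc1a itself was not varied. The ribosomal protein median of 0.30 was larger, so the rise was not particular to oxidative phosphorylation genes.

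The higher fetal liver genes may extend to the imprinted growth network to which H19 belongs. The 7 measured imprinted genes outside the other lists and outside the authors' calls had a median log2 ratio of 0.48 against a random range of -0.23 to 0.44, with the cell cycle inhibitor Cdkn1c at 0.780 and 2.62 FPKM and Gnas on the other side at 306 and 246 FPKM; with all 10 members, Peg3 (0.316 and 4.99 FPKM) included, the median was 0.61. Cdkn1c and Grb10 (0.717 and 1.39 FPKM, log2 ratio 0.48), whose ratio set the median, passed the minimum of 1 FPKM only through the Alb-Cre library. That minimum favours genes higher in that library, so the imprinted median does not decide. The margin is narrow and the list short. The stellate and endothelial medians of 0.48 and 0.47 were of the same size, so a changed share of cells stays open for the imprinted genes too. A stress hormone difference between the pools could raise Mt1, Mt2, Sgk1, Tat and Ddit4, and the full list of 22 glucocorticoid-induced genes had a median of 0.96. Both of these lists were drawn up with many of their values known, and the 9 glucocorticoid-induced members outside the other lists and the authors' calls had a median of 0.093, within the random range of -0.32 to 0.14, with Fkbp5 at 12.4 and 16.7 FPKM and Tsc22d3 at 64.0 and 66.2 FPKM. Leaving out the called genes removed members because they differed, so this value does not decide, and a glucocorticoid response stays open.

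Sex-biased genes were shifted towards the female pattern. Female livers in the Alb-Cre pool would lower Y-linked genes by at least as much as the male-biased genes, whose median was -1.25, and raise Xist, but the Y-linked median was -0.29 and Xist was 0.0246 and 0.0166 FPKM. A lower share of hepatocytes would lower female-biased genes too, since hepatocytes express them, but their median was 1.59. A difference in growth hormone signalling between the genotypes, to which the lower Ghr, Igf1 and Igfals would belong, stays open as a hypothesis that was not tested; of the genes that growth hormone induces, Cish (19.1 and 9.98 FPKM) was lower in value and Socs2 (8.58 and 14.5 FPKM) higher, and the axis list's median of -0.21 lay within the random range but at -0.44, below it, with a minimum of 5 FPKM. With 1 pool per genotype, a difference between these groups of mice that has nothing to do with Akt1 stays open too.

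Immune and stromal markers were higher together, and a lower share of hepatocytes would raise all of them alike. The monocyte and macrophage median exceeded the endothelial median by 0.68 (95% bootstrap interval over genes 0.25 to 1.03). The difference was 0.29 (-0.088 to 0.85) with no minimum and 0.40 (-0.030 to 0.65) with a pseudocount of 5 FPKM. These settings were tried after the first value was seen. A changed share cannot be told apart here from a difference in these cells. The resident Kupffer median exceeded the endothelial median by 0.39 (0.096 to 0.73), with an interval above 0 under every setting tried. Its excess over the stellate median was 0.38 (0.095 to 0.70), but that interval included 0 with a pseudocount of 0.1 FPKM or a minimum of 5 FPKM. Kupffer and endothelial markers thus did not rise alike, but genes are not independent. The stellate and endothelial medians differed by 0.0064 (-0.11 to 0.27), or by 0.16 (0.019 to 0.43) with a pseudocount of 0.1 FPKM, so a changed share cannot be told apart there either. Blood left after perfusion cannot be told apart from resident cells, because the 3 measured erythroid genes had a median of -0.025 and went both ways, with Alas2 at -1.46, which was first tested alone and argued against blood before the test was widened to all 3, and Hbb-b2 at 0.89. More macrophages or more expression per macrophage in livers labelled as carrying Alb-Cre was not tested.

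Short RNA features filled most of the largest ratios, and unstable estimates for very short features are a candidate explanation. Of 188 measured, 68 (36.2%) were listed at 0 in 1 library and at 1 FPKM or more in the other, 34 in each direction, against 6 of 11218 other genes (0.0535%). Mature microRNAs and snoRNAs are shorter than usual library fragments, so these values say little about either genotype, and no biological explanation was tested.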
